A study of Homo sapiens with 8 samples.

How the data were processed

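RNA-seq was carried out on 8 libraries from 2 human cell lines, LX-2 and QSG, each transfected for 48 h with a mimic of the microRNA miR-150-5p or with a control. The labels describe LX-2 as a hepatic stellate cell line and QSG as a normal liver line, and place both at passages 10-15. The 4 groups, a control and a mimic group in each line, held 2 libraries each. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The labels were taken as given. The labels alone do not exclude an exchange of QSG control and mimic labels, and a full one would turn the sign of each QSG fold change. The sequence of the control oligonucleotide is not given in the sources used here.

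Per the labels' protocols and the series' design text, total RNA was extracted with Trizol, libraries were made with the Illumina TruSeq RNA kit v2, and paired-end reads of 100 nucleotides were aligned with TopHat 2.0.10 to the human genome hg38. The submitters' processing notes also name hg19, so the build behind the counting is open. The deposited tables hold no coordinates. The authors scaled read counts to RPKM (reads scaled to exon length and to the mapped reads of the library) and deposited 1 table of RPKM values per line. The annotation, the counting tool and the treatment of reads shared between near-identical genes are not given in the sources used here, nor is any use of strand. Values of genes with a close copy or an overlapping gene are therefore uncertain, among them those of IFITM1, HLA-B, HLA-C and histone genes, and only the clearest cases are marked where they appear.

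RPKM is scaled within each library, so a rise of abundant genes lowers all others slightly, and changes are relative to the other genes of the same library. Whole reads could not be recovered from the low values: the ratios of low genes between pairs of libraries fell into 1 common step for 1.74 to 6.38% of genes in most pairs and for 15.0 to 18.1% in the 3 pairs among both QSG controls and QSG mimic 2. Sequencing depth is thus unknown, and no counting interval or detection floor is given. An exact 0 is reported as listed at 0.

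Each table had 19918 named rows. In 28 of them the gene name had been turned into a spreadsheet date, and these rows were left out, which leaves 19890 genes. The QSG table also held 1 blank row. Of the 19890 genes, 19086 were matched by symbol or synonym to GENCODE 44 (hg38), 18609 had an annotated 3' UTR and 804 had no match. Coordinates are from GENCODE 44 and not from the deposited tables.

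Changes were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), within each line's own table, with empirical Bayes moderation, an intensity trend and Benjamini-Hochberg adjustment at 0.05. Genes entered with an RPKM of at least 1 in at least 2 of the 4 libraries. Fold changes are the mimic mean minus the control mean on that log2(RPKM + 1) scale, which understates the change of low genes. Whether the response differed between the lines was tested as an interaction over all 8 libraries, for genes past the filter in both lines. That test takes 1 spread per gene shared by both lines, although replicates lay further apart in LX-2. The median absolute difference between controls was 0.105 in LX-2 and 0.0559 in QSG. The lines have their own controls, so the comparisons share no library. The overlap of the calls was tested per direction with a one-sided Fisher's exact test.

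The design, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule takes, per line, the 12 largest rises and falls past the threshold whose libraries do not overlap, or up to 6 genes with the smallest p per direction where fewer pass. It adds up to 4 members per list, 11 genes linked to miR-150-5p or fibrosis in either line, and the 6 largest differences between the lines each way. Results for 2 genes are not reported here. The 24 lists cover reported miR-150-5p targets, collagens, stellate cell activation, matrix proteases, integrins, TGF-beta targets, NF-kappaB cytokines, interferon-stimulated genes, p53 targets, apoptosis, mitosis, DNA replication, cholesterol synthesis, the unfolded protein response, hypoxia and glycolysis, microRNA machinery, ribosomal proteins, mitochondrially encoded genes, and markers of hepatocytes, biliary, squamous, mesenchymal, endothelial and leukocyte cells. Lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, which asks whether a list moves one way without comparing it with other genes.

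Seed matches of miR-150-5p (bases 2 to 8) were sought in the longest annotated 3' UTR of each gene. The 8mer is TTGGGAGA, the 7mer-m8 TTGGGAG, the 7mer-A1 TGGGAGA and the 6mer TGGGAG. The test fixed beforehand compared genes with a 7mer-m8 or an 8mer against genes with no match by camera. It also ranked TTGGGAG among heptamers of the same bases in another order, of which 104 had at least 100 genes, fewer than the 1000 planned. The 8mer alone was an alternative fixed beforehand, but Fisher's exact test of 8mers among the called genes was not. Chosen after the data were seen were a removal of each library's trend against transcript GC, a regression on 3' UTR GC and length, transcript GC and expression, a scan of every heptamer present in at least 100 genes (15842 in LX-2, 15788 in QSG), tests of the heptamers AGTACAA and TACCAGT, and lists of antigen presentation and contractile genes. Bootstrap standard errors used 1000 draws with Python 3.11.15 and numpy 2.4.6.

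The fixed alternatives were a pseudocount of 0.1, no filter or a filter at 5 RPKM, median centring, quantile normalization, no intensity trend, a replicate block, 1 fit over all 8 libraries, a 1.5-fold threshold, any annotated 3' UTR and the leaving out of each library in turn. On simulated data with 100 genes changed at each fold, the LX-2 test found 70 of the 1.5-fold and 99 of the 2-fold changes among 10714 genes with 11 false calls. The QSG test found 94 and 100 among 10318 genes with 11 false calls, and the test of the difference 51 and 97 among 9533 genes with 7 false calls. The simulated errors were normal and independent between genes, with spreads drawn from each fit's own model. Genes of a real library can deviate together, so these counts describe the model and not these libraries.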

Results

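Gene expression was measured by RNA-seq in LX-2, a human hepatic stellate cell line, and in QSG, which the labels call a normal liver line. Stellate cells are the main matrix-producing cells of the fibrotic liver. Both lines were taken 48 h after transfection with a miR-150-5p mimic, a double-stranded oligonucleotide that supplies the mature microRNA UCUCCCAACCCUUGUACCAGUG (22 bases), or with a control, with 2 libraries in each of the 4 groups. The series asks whether the action of this microRNA in liver fibrosis depends on the cell type. The values were RPKM as deposited, summing to 233423 to 251338 per library, with 14483 to 14588 genes above 0 in each. The 10 most abundant genes held 6.31 to 7.10% of the RPKM in LX-2 libraries and 10.6 to 11.2% in QSG libraries. Replicates correlated across genes at 0.9936 to 0.9975. Between control and mimic libraries the correlation was 0.9784 to 0.9863 in LX-2 and 0.9968 to 0.9971 in QSG. Genes are not independent replicates, so these describe the libraries only.

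The control libraries of the lines differed in marker genes, which are set side by side here although each line was scaled in its own table. In LX-2 controls 12 of 17 mesenchymal and stellate markers were at 1 RPKM or more, led by the intermediate filament gene VIM at 1113 RPKM, and 1 of 22 hepatocyte markers was (CPS1, 12.7 RPKM). In QSG controls 4 of 22 hepatocyte markers reached 1 RPKM, led by the urea cycle gene CPS1 at 312 RPKM. The others were low, ALB at 2.45, APOA2 at 2.42 and FGB at 1.13 RPKM, and the median of the 22 was 0.1375 RPKM. The biliary keratin gene KRT7 stood at 355 RPKM and VIM at 168 RPKM. These markers do not establish QSG as a hepatocyte line, and its identity as a normal liver line rests on the labels. Of 12 biliary and simple epithelial markers 4 reached 1 RPKM in each line, and of 12 squamous markers 3 did in LX-2 and 5 in QSG. Of 10 endothelial markers 2 did in LX-2 and 1 in QSG, and of 14 macrophage and leukocyte markers 2 did in LX-2 and 1 in QSG. The mitochondrially encoded genes were not analysed here.

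In LX-2 cells the mimic libraries held far more mRNA of interferon-stimulated genes, the antiviral genes that cells switch on after interferon or viral RNA. Of 32 measured members of the list (35 listed), 31 rose, which was also the number adjusted over the list alone. Their median log2 fold change was 2.21 and their mean 2.41, and the remaining member, IRF1, had a log2 fold change of 0.12. MX2, a dynamin-like antiviral GTPase gene on chromosome 21 (41361999-41409393), went from 1.33 ± 0.0522 RPKM in controls to 53.3 ± 6.65 RPKM with the mimic (SD, n = 2), a log2 fold change of 4.54 (SE 0.105, adjusted p = 1.06e-06). IFI6, on chromosome 1 (27666064-27672212), rose from 27.5 ± 6.33 to 631 ± 194 RPKM (SD, n = 2; log2 fold change 4.45, SE 0.213). The oligoadenylate synthetase genes OAS2 (0.832 to 35.7 RPKM), OAS1 (0.545 to 16.2 RPKM) and OAS3 (7.84 to 67.6 RPKM), which code for sensors of double-stranded RNA, rose by 4.31, 3.47 and 2.95 on the log2 scale. MX1 rose by 4.09, IFI44L by 3.80, IFIT1 by 3.56, IFITM1 by 3.52, the ubiquitin-like modifier gene ISG15 by 3.35 and IFI44 by 3.04. IFI44L was at 0.165 RPKM and MX1 at 0.583 RPKM in controls, so on this scale their changes are understated.

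Among the RNA sensors, DDX58 rose by 2.14 and IFIH1 by 2.37 on the log2 scale. Of the factors that carry the interferon signal to the nucleus, STAT2 rose by 1.18 and IRF9 by 1.93. Camera gave the list an adjusted p of 2.0e-69, and it passed under 14 of 15 alternatives (range of adjusted p 7.5e-100 to 0.436). The exception was the estimated correlation, with adjusted p = 0.436. Fry gave an adjusted p of 0.0178. In the same LX-2 libraries the macrophage marker CD68 rose from 14.2 to 24.6 RPKM (log2 fold change 0.76, adjusted p = 0.00805, but 0.0794 without mimic 1 and 0.0792 without mimic 2), CD14 went from 1.93 to 1.16 RPKM (adjusted p = 0.109), and the median of the 14 macrophage and leukocyte markers was 0 RPKM in both mimic libraries.

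**Figure D1:**
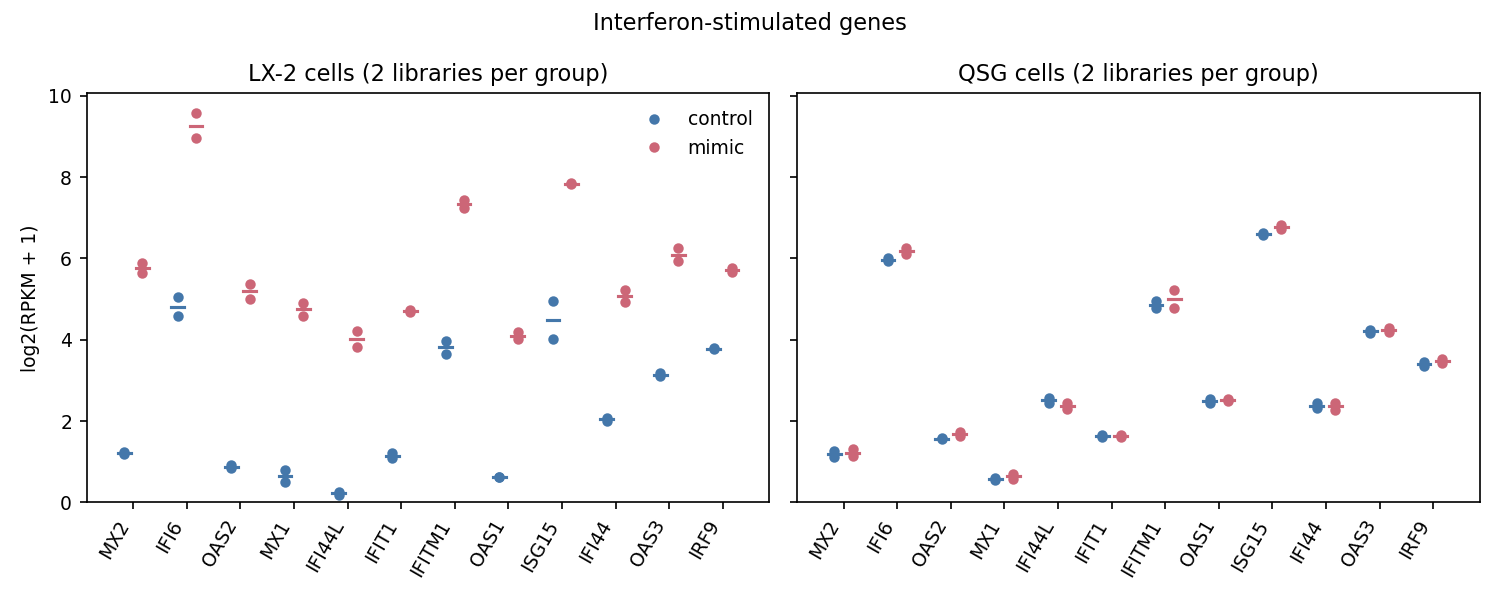
Levels of 12 interferon-stimulated genes on the y axis, as log2(RPKM + 1), in LX-2 (left) and QSG (right) cells; points are libraries (2 per group, control blue, mimic red) and short lines are group means. In LX-2 the mimic libraries lie above the controls for each gene shown, by 4.54 for MX2, while in QSG both groups lie close together.

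Genes of fibrosis moved in both directions in LX-2. Of 25 measured genes of stellate cell activation and myofibroblasts, 3 rose, 3 fell and 19 did not pass (3 and 4 adjusted over the list alone). The list as a whole did not pass (adjusted p = 0.642), with a median of 0.02 and a mean of -0.003 while camera pointed up. LOXL2, a collagen cross-linking enzyme gene, went from 63.0 ± 4.62 to 121 ± 2.19 RPKM (SD, n = 2; log2 fold change 0.94, SE 0.0889, adjusted p = 0.00102), FBN1, the gene of the microfibril protein fibrillin 1, rose by 0.53 and the calcium-binding protein gene S100A6 by 0.44. The genes that fell belong to the contractile apparatus. ACTA2, the gene of alpha smooth muscle actin and the usual marker of stellate cell activation, went from 2.56 ± 0.099 to 1.12 ± 0.196 RPKM (SD, n = 2; log2 fold change -0.75, SE 0.106, adjusted p = 0.00854), TAGLN from 182 to 111 RPKM (log2 fold change -0.70) and the myosin light chain gene MYL9 from 346 to 212 RPKM (log2 fold change -0.69). LOXL2 passed under 12 of 12 alternatives. Without mimic 1, ACTA2 (adjusted p = 0.0972), TAGLN (0.149), MYL9 (0.161), FBN1 (0.156) and S100A6 (0.221) missed the threshold, as did TAGLN (0.0975), MYL9 (0.0855), FBN1 (0.0739) and S100A6 (0.149) without mimic 2 and S100A6 (0.0839) without control 1.

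Among 16 measured matrix proteases and inhibitors 3 rose and 1 fell (4 and 1 adjusted over the list alone; list adjusted p = 0.0561). ADAMTS1 rose by 0.96 (5.45 to 11.5 RPKM), ADAM9 by 0.84 (42.0 to 76.1 RPKM) and the protease inhibitor gene TIMP3 by 0.44, whereas the gelatinase gene MMP2 fell by 0.43 on the log2 scale (22.0 to 16.0 RPKM). None of 15 measured collagen genes passed with limma, either over all genes or adjusted over the list alone (median 0.10, list adjusted p = 0.293). COL1A1 was at 275 ± 26.9 RPKM in controls and 271 ± 6.39 RPKM with the mimic (SD, n = 2; adjusted p = 0.952). COL4A1 had a log2 fold change of 0.42 (adjusted p = 0.0737). Of 19 integrin and focal adhesion genes ITGB1 rose by 0.55 (3 higher and 1 lower adjusted over the list alone; median -0.11, list adjusted p = 0.670), and none of 16 TGF-beta target genes passed by either adjustment (median -0.07, which reached 0.001 after removal of the trend against transcript GC, list adjusted p = 0.609). TGFB1 itself had a log2 fold change of -0.22 (adjusted p = 0.283), which was -0.10 without LX-2 control 1, -0.34 without LX-2 control 2 and -0.07 after removal of GC trends. After that removal COL1A1 was at 0.12. The collagen list passed without LX-2 control 1 (adjusted p = 0.0105) and after removal of GC trends (0.00993; range over alternatives 0.00993 to 0.993). The protease list did so without LX-2 control 1 (adjusted p = 0.0105) or LX-2 mimic 2 (0.0126), after removal of GC trends (0.0203) and with a filter at 5 RPKM (0.0335; range 0.0105 to 0.732). TIMP3, MMP2 and ITGB1 missed the threshold without control 1 (adjusted p from 0.0965 to 0.135), mimic 1 (0.198 to 0.286) or mimic 2 (0.130 to 0.226).

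**Figure D2:**
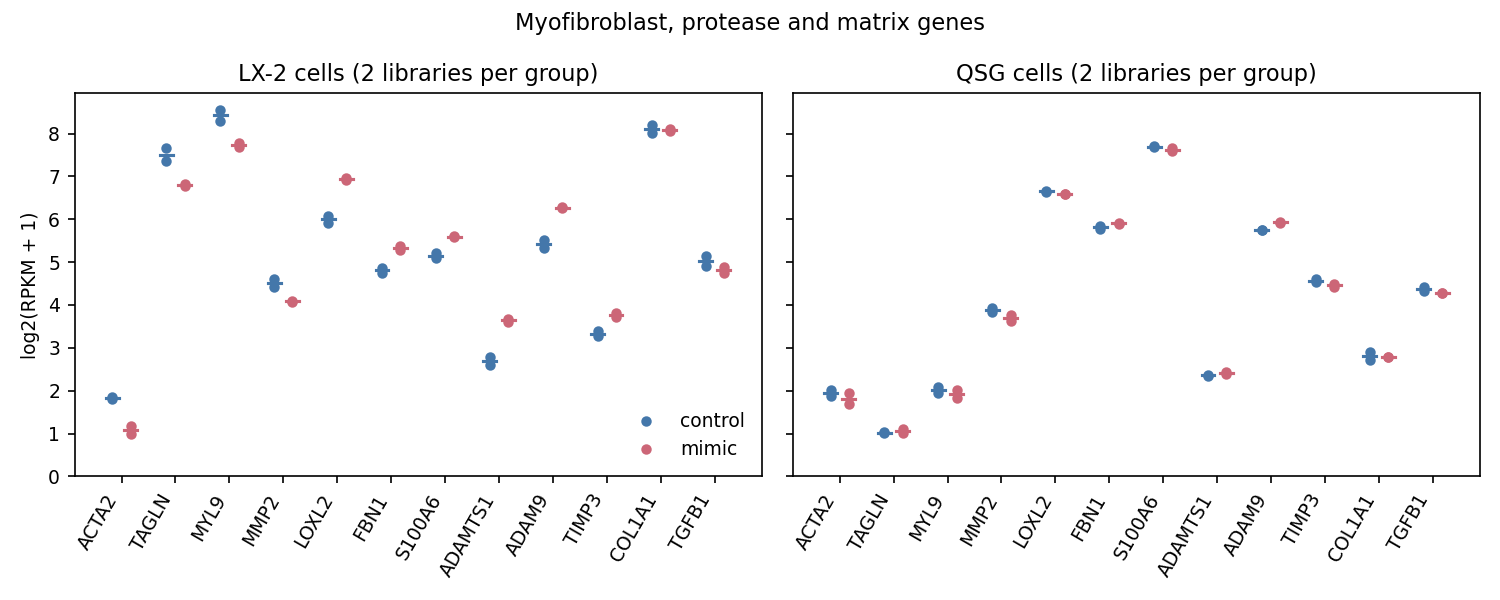
Levels of myofibroblast, protease and matrix genes on the y axis, as log2(RPKM + 1), in LX-2 (left) and QSG (right); points are libraries (2 per group, control blue, mimic red) and short lines are group means. In LX-2, ACTA2, TAGLN, MYL9 and MMP2 lie lower and LOXL2, FBN1, S100A6, ADAMTS1, ADAM9 and TIMP3 higher with the mimic, while COL1A1 and TGFB1 did not pass.

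Other LX-2 lists moved less. Of 22 NF-kappaB cytokine genes 1 passed over all genes, the chemokine gene CCL5 at a log2 fold change of 1.65 (0.990 to 5.28 RPKM), and 7 passed adjusted over the list alone. The cytokine genes IL6 (0.53) and CXCL8 (0.55) did not pass over all genes. The NF-kappaB list passed with a median of 0.23 (adjusted p = 0.000497), not with an estimated correlation (adjusted p = 0.879, the highest of 15 alternatives that reach down to 8.4e-10). It also missed with fry (0.510) and without LX-2 control 2 (median 0.15, adjusted p = 0.241) or LX-2 mimic 1 (median 0.07, adjusted p = 0.0638). All but 2 of 45 ribosomal protein genes had a negative fold change (median -0.17). None passed with limma by either adjustment, and the list passed (adjusted p = 0.000497), but not with an estimated correlation (adjusted p = 0.879, range 6.6e-08 to 0.879), with quantile normalization (median -0.09, adjusted p = 0.0555), with fry (0.510) or without LX-2 mimic 1 (median -0.07, adjusted p = 0.256). Of 30 DNA replication genes 2 fell, TYMS by 0.50 and CCNE1 by 0.45 on the log2 scale (3 adjusted over the list alone), with a list median of -0.08 (adjusted p = 0.0385). That list missed with an estimated correlation (adjusted p = 0.732, range 0.0154 to 0.732), with median centring (0.0538), quantile normalization (0.0555), the replicate block (0.0528) or fry (0.110), and without LX-2 control 2 (0.236), mimic 1 (0.0519) or mimic 2 (0.121), so that it passed under 7 of 15 alternatives. TYMS missed without mimic 1 (0.101) or mimic 2 (0.153), and CCNE1 without control 1 (0.0891), mimic 1 (0.210) or mimic 2 (0.217).

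Single genes passed in several lists that did not pass as a whole. The cyclin gene CCNA2 rose by 0.71, 1 of 29 mitotic genes (list adjusted p = 0.293), and GADD45A rose by 0.79, 1 of 22 p53 target genes (list adjusted p = 0.509, but 0.0335 with a filter at 5 RPKM; 2 higher and 2 lower adjusted over the list alone). BIRC2 rose by 0.50 among 20 apoptosis genes (list adjusted p = 0.670). Among 24 cholesterol synthesis genes STARD4 rose by 0.51 (list adjusted p = 0.781). None of 26 unfolded protein response genes (list adjusted p = 0.670), 29 hypoxia and glycolysis genes (0.781), 23 genes of the microRNA machinery (0.627) or 12 mesenchymal markers (0.781) passed in limma over all genes. The hypoxia genes BNIP3 and PDK1 did so under some alternatives, BNIP3 with a filter at 5 RPKM (adjusted p = 0.0479), without LX-2 control 1 (0.0428) and, like PDK1, with each of 3 scalings (0.0114 to 0.0164, and 0.0349 to 0.0478 for PDK1), and PDK1 without LX-2 control 2 (0.0229). KDM3A did after removal of GC trends (0.0474). The hypoxia list had a median of -0.07 and the mesenchymal list one of -0.03, or 0.05 after quantile normalization, although camera pointed up for both. Other genes among the largest falls were LCP1 (-1.05), ATP9A (-0.90), ACOT8 (-0.84), NT5DC2 (-0.83), the ketone metabolism gene ACAT1 (-0.83) and TTLL12 (-0.80). CD99 (log2 fold change 3.09) lies in a region shared by the sex chromosomes, and JMJD7-PLA2G4B (-0.84) is a readthrough of neighbouring genes, so both values are uncertain. Without mimic 1 the adjusted p was 0.068 for CCNA2, 0.0595 for GADD45A, 0.277 for BIRC2, 0.138 for STARD4, 0.193 for ACOT8, 0.109 for NT5DC2, 0.132 for TTLL12 and 0.168 for JMJD7-PLA2G4B. Without mimic 2 it was 0.0861 for STARD4 and 0.0907 for TTLL12, and without control 1 it was 0.0633 for BIRC2.

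In all, 381 of 10714 genes tested changed in LX-2, 228 up and 153 down, with 66 up and 4 down by 2-fold or more. At an unadjusted p below 0.05 there were 2154. The control and mimic values did not overlap for 5668 genes (52.9%), against 33.3% by chance. The number of calls rested on few libraries: it was 94 without mimic 1 (81 up, 13 down), 145 without mimic 2 (113 up, 32 down) and 1151 without control 2, where the balance turned to 356 up and 795 down. The 12 largest rises passed under all 12 alternatives with a test, except ISG15, which missed without a filter on low values (adjusted p = 0.0642, the highest of its range). Of the 381 genes, 93 were still called without mimic 1, 132 without mimic 2 and 73 without the filter.

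Whether the mimic lowered genes with a miR-150-5p site was asked from 3' UTR sequence. In the test fixed beforehand, 3032 LX-2 genes with a 7mer-m8 or 8mer had a mean log2 fold change 0.04 below that of 5006 genes without a match (difference -0.0353), which did not pass (camera p = 0.110, or 0.221 with an estimated correlation). It passed without LX-2 control 1 (camera p of 0.0329) or LX-2 mimic 1 (camera p of 0.0371). Against all other genes, those with TTGGGAG differed by -0.0213, and 7 of 104 other orderings of its bases lay at or below that. After a regression on 3' UTR GC and length, transcript GC and expression, chosen after the data were seen, this difference was -0.0264 and none of the 104 orderings lay at or below it. TGGGAGA and TTGGGAG then ranked 1 and 2 from the lowest of 15842 heptamers, by the difference over its standard error. Before the regression they ranked 253 and 1616 from the lowest. The regressed difference of LX-2 seed-site genes from genes without a match, -0.0270, still did not pass (camera p of 0.309). Genes with the full 8mer, an alternative also fixed beforehand, were lower. The 705 such genes differed by -0.0895 from genes without a match (p = 6.0e-05, or 0.0181 with an estimated correlation). The 8mer was present in 43 of 153 genes that fell (28.1%), in 10 of 227 that rose (4.41%) and in 652 of 10244 that did not pass (6.37%). The odds ratio of fallen against unchanged genes was 5.75 (95% interval 3.91 to 8.33; two-sided Fisher's exact test, p = 1.65e-16). That test of the calls was not fixed beforehand. It takes genes as independent although all come from the same 4 libraries, so its interval and p-value only describe these genes. In QSG the corresponding differences were -0.0005 (2906 against 4846 genes, camera p of 0.981) and -0.0033 for the 8mer (678 genes, camera p of 0.704).

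Several of the largest LX-2 falls carried such sites. PERP, a gene of desmosomes and a p53 target, fell from 11.6 ± 0.315 to 5.08 ± 0.237 RPKM (SD, n = 2; log2 fold change -1.06, adjusted p = 0.000445), and its 3' UTR holds an 8mer in the last of 3 exons, on the minus strand of chromosome 6 (138091899-138091906, hg38), in the context TGCTAAAATAATTTGGGAGAAAATATTT. FEZ2 fell by 0.81 on the log2 scale (8mer on chromosome 2, 36552793-36552800, minus strand, exon 6 of 6) and RBPMS2 fell by 0.94 (8mer on chromosome 15, 64739976-64739983, minus strand, exon 8 of 8). KCTD20 fell from 14.7 to 5.52 RPKM (log2 fold change -1.27), with 3 7mer-m8 sites between 36490291 and 36490610 on chromosome 6. RAB6A, a Golgi transport GTPase gene, showed the largest fall, from 67.3 ± 3.64 to 26.8 ± 0.219 RPKM (SD, n = 2; log2 fold change -1.29, SE 0.0821, adjusted p = 8.62e-05), and holds 7mer-A1 sites at 73677126-73677132 and 73676157-73676163 on chromosome 11. Its value is uncertain, since RAB6C is a near-identical copy.

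Of 18 measured genes reported elsewhere as miR-150-5p targets, 2 fell in LX-2 (2 adjusted over the list alone; median -0.08, list adjusted p = 0.509). CBL, a ubiquitin ligase gene, fell by 0.52 on the log2 scale and has 8mers at 119301311-119301318 and 119307682-119307689 on chromosome 11, in exon 16 of 16. PRKCA, a protein kinase C gene, fell by 0.54 on the log2 scale. CBL and PRKCA missed the threshold without mimic 1 (adjusted p = 0.158 and 0.0933) or mimic 2 (0.0907 and 0.107). SP1, with 8mers at 53412719-53412726 and 53415193-53415200 on chromosome 12, had a log2 fold change of -0.16 (22.1 to 19.7 RPKM, adjusted p = 0.30), and ZEB1, with an 8mer at 31527676-31527683 on chromosome 10, one of -0.22 (adjusted p = 0.232). NOTCH3 (-0.09, adjusted p = 0.658, and 0.06 after removal of GC trends) and CXCL1 (-0.02, adjusted p = 0.950, and 0.12 without LX-2 control 1) did not pass. MYB, CXCR4, SPI1 and COL4A4 were below the filter in LX-2.

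A scan of all heptamers, chosen after the data were seen, gave another word higher with the mimic. Genes whose 3' UTR holds AGTACAA differed from the rest by 0.113 in LX-2 (rank 2 of 15842 heptamers) and by 0.0223 in QSG (rank 2 of 15788), just after the overlapping GTACAAA. The octamer AGTACAAA was present in 42 of 227 genes that rose in LX-2 (18.5%), in 1 of 153 that fell and in 424 of 10244 that did not pass (4.14%; odds ratio 5.26, 95% interval 3.62 to 7.50, two-sided Fisher's exact test, p = 1.63e-15). LOXL2, ADAMTS1, ADAM9, CCNA2, PARP9 and IFIT5 are among those 42. AGTACAA was picked from the same fold changes that gave the calls, so its enrichment among the rises follows in part from that choice. The odds ratio and its p-value make no allowance for this and only describe these genes.

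**Figure D3:**
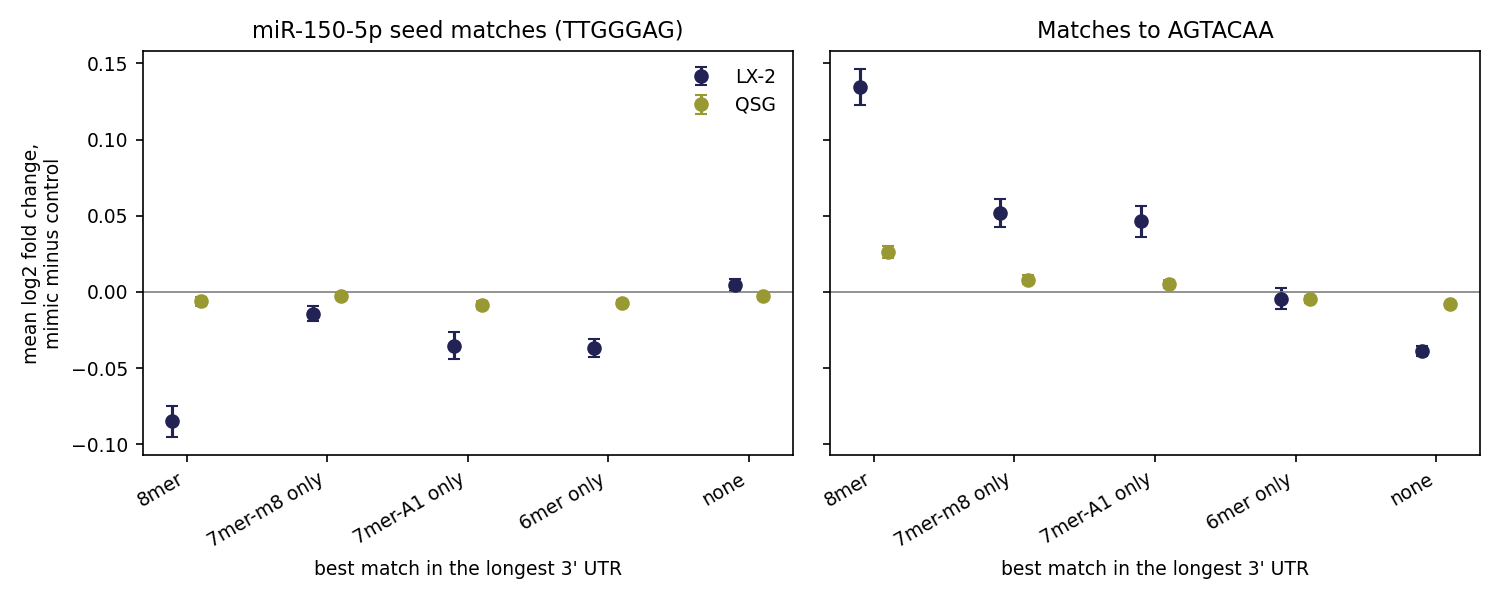
Mean log2 fold change (y axis, mimic minus control) of genes by the best match in their longest 3' UTR (x axis) to the miR-150-5p seed site (left) or to AGTACAA (right), in LX-2 (dark) and QSG (olive); error bars are bootstrap standard errors. The LX-2 mean is -0.08 for miR-150-5p 8mers and 0.13 for the octamer AGTACAAA, and the QSG means stay between -0.01 and 0.03.

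In QSG cells, with the labels taken as given, few transcripts moved. SMN1, the survival of motor neuron gene, went from 10.96 ± 0.318 to 4.73 ± 0.289 RPKM (SD, n = 2; log2 fold change -1.06, SE 0.0593, adjusted p = 0.00204), and it was the 1 gene of 10318 that passed. It is nearly identical to SMN2, so the split of reads between them leaves this value uncertain, and it missed without a filter on low values (adjusted p = 0.207). The next smallest p-values belonged to IGFBP3, which codes for a carrier of insulin-like growth factors (103 to 71.0 RPKM, log2 fold change -0.54), and the hypoxia-induced gene NDRG1 (151 to 101 RPKM, -0.57), both at an adjusted p of 0.0711. Below these, ERRFI1 (-0.37), NDUFAF2 (-0.36) and BAMBI (-0.35) were lower and HIST1H2BH (0.56), C18orf32 (0.43), UQCC2 (0.36), CDK6 (0.34), CCNA2 (0.30) and BMP2 (0.30) were higher, at adjusted p from 0.176 to 0.225, which did not pass. At an unadjusted p below 0.05 there were 904 genes, and control and mimic values did not overlap for 4022 (39.0%, against 33.3% by chance). With limma the number of calls was 4 without QSG control 1, 3 without control 2 and 3 without mimic 1. IGFBP3 and NDRG1 passed with a filter at 5 RPKM (adjusted p = 0.0252 for both), without control 1 (0.0144 for both) and without mimic 1 (0.0186 and 0.0169).

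No list member passed over all QSG genes with limma, while 9 of 20 lists passed with camera at small effects. None of the 9 held with an estimated correlation (adjusted p = 0.611 for 8 of them and 0.619 for integrins, the highest over the alternatives for each) or with fry (0.189 to 0.476). Of 15 alternatives collagens passed under 6, ribosomal proteins under 8, the unfolded protein response under 9, and hypoxia and stellate activation under 13. Of 31 hypoxia and glycolysis genes, 30 had a negative fold change (median -0.11, adjusted p = 7.5e-15, over alternatives 3.5e-17 to 0.611), and 11 passed adjusted over the list alone. NDRG1, EGLN3 (-0.46), ENO2 (-0.32) and the glucose transporter gene SLC2A3 (-0.28) had the smallest p. The lists of stellate activation (19 genes, median -0.08, adjusted p = 0.00404, 1 gene adjusted over the list alone), reported miR-150-5p targets (18, -0.08, 0.00519, 0 genes), squamous markers (5, -0.16, 0.00741, 1), integrins (19, -0.02, 0.0215, 1) and collagens (10, -0.05, 0.0383, 2) leaned down. Ribosomal protein genes did too (45, -0.03, 0.0149, 0 genes), with a median of 0 after quantile normalization. Mitotic genes (29, 0.04, 0.00404, 1) and unfolded protein response genes (26, 0.02, 0.0215, 0) leaned up.

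Single QSG libraries ended some of these list calls. Without control 1 the adjusted p was 0.226 for collagens, 0.0720 for squamous markers and 0.226 for the unfolded protein response. Without control 2 it was 0.12 for ribosomal proteins and 0.145 for integrins, without mimic 1 it was 0.0588 and 0.137 for the same lists, and without mimic 2 it was 0.0762 for mitotic genes (median -0.01), 0.311 for collagens and 0.269 for the unfolded protein response. The interferon list did not pass (29 genes, median 0.03, adjusted p = 0.0913), and IFI6 (61.8 to 71.8 RPKM) and ISG15 (96.1 to 108 RPKM) each had an adjusted p of 0.400. That list passed without mimic 1 (adjusted p = 0.004, the lowest of a range that reaches 0.869). The lists of NF-kappaB cytokines (adjusted p = 0.503), TGF-beta targets (0.284), proteases (0.209), p53 targets (0.597), apoptosis (0.503), DNA replication (0.656), cholesterol synthesis (0.325), microRNA machinery (0.503), hepatocyte markers (0.597) and mesenchymal markers (0.209) did not pass. In QSG, CXCR4, a chemokine receptor gene and reported target, had a log2 fold change of -0.13 (61.8 to 56.2 RPKM, adjusted p = 0.510). SP1 (-0.01), COL1A1 (-0.03), CXCL1 (-0.37), ZEB1 (-0.12), NOTCH3 (-0.14), ACTA2 (-0.13) and TGFB1 (-0.09) had adjusted p from 0.563 to 0.955. Single libraries moved some of these: CXCL1 was at -0.11 without control 1 and -0.63 without control 2, COL1A1 at 0.06 and -0.13, and ACTA2 at 0.01 without mimic 1 and -0.26 without mimic 2. SPI1 was listed at 0 in the 4 QSG libraries, and COL4A4 and MYB were below the filter.

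Whether the lines responded differently was tested directly, with 1 spread per gene shared by both lines. The responses of 248 of 9533 genes differed, 155 more positive and 93 more negative in LX-2, with 52 and 3 by 2-fold or more, and 1633 had an unadjusted p below 0.05. The interferon genes led: the LX-2 response exceeded that of QSG by 4.51 for MX2 (SE 0.145, adjusted p = 2.9e-07), 4.24 for IFI6, 4.19 for OAS2, 3.93 for IFI44L, 3.56 for IFIT1 and 3.44 for OAS1. Of 28 interferon-stimulated genes tested, 27 differed (27 adjusted over the list alone), and the list passed with an estimated correlation too (median 2.12, adjusted p = 5.0e-69, or 0.0336 estimated). RAB6A (-1.12), KCTD20 (-1.11), ACOT8 (-1.06), NT5DC2 (-0.85), BRI3BP (-0.78) and SLC35B4 (-0.77) had the most negative differences. ACOT8 missed without any 1 of 6 libraries (adjusted p from 0.0533 without LX-2 control 1 to 0.149 without QSG mimic 1), and NT5DC2 without LX-2 mimic 1 (0.0811) or any QSG library (0.0618 to 0.117). LOXL2, ADAMTS1, ADAM9, FBN1, S100A6, TIMP3 and TAGLN also differed between the lines, while ACTA2 (-0.62, adjusted p = 0.0747), MYL9 (-0.59, 0.0602) and MMP2 (-0.25, 0.317) did not pass that test. Genes with a miR-150-5p 8mer differed by -0.0827 more in LX-2 (626 against 4479 genes, camera p of 0.000117, or 0.0342 with an estimated correlation), and those with a 7mer-m8 or 8mer by -0.0326 (camera p of 0.109).

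Of 18 lists, 8 differed between the lines. Matrix proteases (median 0.26, adjusted p = 0.00426), NF-kappaB cytokines (0.33, 0.00392), collagens (0.20, 0.0355), stellate activation (0.11, 0.0266) and hypoxia genes (0.08, 0.00426) were higher in LX-2 relative to QSG besides the interferon genes. DNA replication (-0.11, 0.0126) and ribosomal protein genes (-0.15, 0.0165) were lower. These 7 did not hold with an estimated correlation (adjusted p from 0.287 to 0.882). Integrins had a median of -0.06 with camera pointing up, and reported targets one of 0.05 with a mean of -0.004 and camera pointing down, neither passing (adjusted p = 0.833 for both). The number of genes that differed was 930 without LX-2 control 2 and 146 without LX-2 mimic 1. Without QSG control 1, control 2, mimic 1 or mimic 2 it was 105, 95, 98 and 109.

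**Figure D4:**
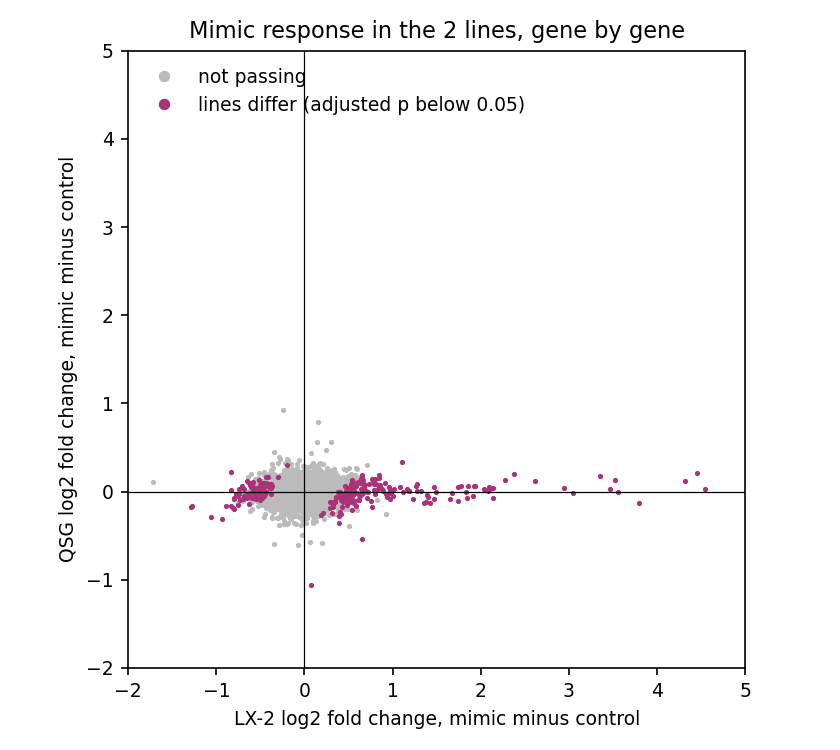
Log2 fold change of each gene tested in both lines, LX-2 on the x axis and QSG on the y axis (mimic minus control); purple points are the 248 genes whose response differed at an adjusted p below 0.05, grey points the others. The purple points spread along the LX-2 axis up to 4.54 and mostly stay closer to 0 on the QSG axis, where SMN1 lies at -1.06 and IGFBP3 at -0.54.

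No gene was called in both lines. Among 9533 genes tested in both, 195 rises and 143 falls of LX-2 met 0 rises and 1 fall of QSG (0 shared against 0.015 by chance for falls, one-sided Fisher's exact test, p = 1). With so few QSG calls this comparison could hardly show sharing. Across genes the fold changes of the lines correlated at 0.088 (Pearson) and 0.093 (Spearman). Of the 143 genes that fell in LX-2, 100 had a negative fold change in QSG (69.9%), as had 70 of the 195 that rose (35.9%), against 50.8% of all genes.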

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

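The tests of leukocyte transcripts, of a response to double-stranded RNA, of replicate spread and of oligonucleotide activity were chosen only after the results they bear on had been seen, as were the removal of GC trends and the regression on 3' UTR and transcript properties.

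The mimic response differed between the lines, by a test of the difference itself, for 248 genes, and the values here are the LX-2 minus the QSG log2 fold change. Among lists the medians were 2.12 for interferon-stimulated genes, 0.33 for NF-kappaB cytokines, 0.26 for matrix proteases, 0.20 for collagens, 0.11 for stellate activation genes and 0.0845 for hypoxia genes. They were -0.11 for DNA replication genes and -0.15 for ribosomal protein genes. With an estimated correlation only the interferon list still differed (adjusted p = 0.0336, against 0.287 to 0.882 for the other 7). Genes with a miR-150-5p 8mer had a difference of -0.0827. Of 59 named genes tested 41 differed. The interferon genes among them were MX2 (4.51), IFI6 (4.24), OAS2 (4.19), IFI44L (3.93), IFIT1 (3.56), OAS1 (3.44), IFITM1 (3.39), ISG15 (3.18), IFI44 (3.06) and OAS3 (2.91). Matrix, adhesion and stellate genes were LOXL2 (1.00), ADAMTS1 (0.90), ADAM9 (0.66), ITGB1 (0.56), TIMP3 (0.56), S100A6 (0.51), FBN1 (0.44) and TAGLN (-0.74). Higher values were also found for the chemokine gene CCL5 (1.74), IGFBP3 (1.19), CD68 (0.94), CDK6 (0.77), NDUFAF2 (0.76), GADD45A (0.65) and STARD4 (0.46). SMN1 (1.14) differed because it was lower with the mimic in QSG. Lower values were found for PRKCA (-0.46), CBL (-0.56), TYMS (-0.57), RBPMS2 (-0.62), FEZ2 (-0.63), ACAT1 (-0.67), TTLL12 (-0.72), ATP9A (-0.73), PERP (-0.77), SLC35B4 (-0.77), BRI3BP (-0.78), NT5DC2 (-0.85), ACOT8 (-1.06), KCTD20 (-1.11) and RAB6A (-1.12).

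Genes with AGTACAA in the 3' UTR were higher in the mimic libraries of both lines, by 0.113 in LX-2 and 0.0223 in QSG. A full exchange of QSG labels would make them lower with the mimic in QSG. The QSG octamer mean was 0.0263 (bootstrap SE 0.00382) as labelled, which argues against a full exchange if these genes respond alike in both lines. An exchange of single QSG libraries stays open. After regression on 3' UTR GC and length, transcript GC and expression the LX-2 difference was 0.0817. These properties, as fitted, did not account for it. It lay above the differences of 209 other orderings of its bases, the highest being 0.0754 for the overlapping GTACAAA. AGTACAA lay above all of these before the regression too and was picked from the same fold changes. Its place among the orderings was thus nearly fixed by that choice and says little about base composition. A candidate explanation is that the control oligonucleotide lowers these genes in the control libraries, as AGTACAA pairs with the seed of the worm microRNA miR-239b, a common negative control, although the control sequence is not given in the sources used here. Octamer genes exceeded heptamer-only genes by 0.0826 (SE 0.0148) in LX-2 and 0.0182 (SE 0.00492) in QSG, as this explanation needs. The reverse complement TTGTACT ranked 3465 and 2928 from the highest. These comparisons could hardly have gone against the explanation, so they carry little weight. The octamer joins AGTACAA and GTACAAA, which led the scan in both lines. Nearly any heptamer lies outside the top 100, the limit set for the reverse complement. An effect of the mimic on the same genes stays open, because no untreated library is used here to separate them, and 42 of 227 LX-2 rises, LOXL2, ADAMTS1 and ADAM9 among them, carry the octamer.

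Interferon-stimulated genes were higher in the LX-2 mimic libraries. A library bias along GC is argued against, since the list median was 2.20 after the removal of GC trends and 31 of 32 members passed. Leukocytes in the mimic libraries are argued against as well: the median of 14 leukocyte markers was 0 RPKM in both. It was 0.00339 RPKM in LX-2 control 1 and 0 RPKM in control 2. In the mimic libraries LYZ was at 0.0798 RPKM at most and PTPRC at 0.00772 RPKM at most. CD68 went the other way, from 14.2 to 24.6 RPKM, while CD14 went from 1.93 to 1.16 RPKM. A response to the double-stranded RNA of the mimic and an effect of its microRNA sequence cannot be told apart. By the labels, 0 libraries hold a mimic of another sequence. The sequence of the control oligonucleotide is not given, so whether the controls hold a microRNA-like oligonucleotide is unknown. The AGTACAA pattern described above is a candidate sign of one, but the comparisons made there could not decide it. Differences between the lines in RNA sensing may also matter, and these were not tested.

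Fewer genes changed in QSG than in LX-2. Wider replicate spread is argued against, since the median absolute difference between QSG controls was 0.0559 against 0.105 in LX-2, and 0.0660 against 0.0914 between mimic libraries. Less oligonucleotide activity in QSG may contribute and stays open: 8mer genes that fell in LX-2 were negative in QSG in 32 of 42 cases (76.2%), against 302 of 584 other 8mer genes (51.7%, one-sided Fisher's exact test, p = 0.00145) but also against 68 of 101 fallen genes without the 8mer (67.3%, one-sided Fisher's exact test, p = 0.198). The miR-150-5p 8mer difference from genes without a match was -0.0033 in QSG and -0.0895 in LX-2. For the octamer AGTACAAA it was 0.0343 in QSG and 0.173 in LX-2. Fold changes of all genes were smaller in QSG too, with a median absolute value of 0.0498 against 0.118. These values therefore cannot tell less oligonucleotide activity from a smaller response. A difference in biology between the lines also stays open and was not tested.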

How the results depend on the processing

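The removal of GC trends and the regression of fold changes were chosen after the data were seen. The number of LX-2 genes changed, 381, became 77 without a filter on low values, 669 with median centring, 593 with quantile normalization, 684 with GC trends removed, 1194 in 1 fit over all 8 libraries and 196 with at least a 1.5-fold change. Leaving out a library gave 94 (without mimic 1) to 1151 (without control 2), where falls came to outnumber rises. In QSG, where 1 gene changed, the count was 0 without the filter, 3 with a filter at 5 RPKM, 0 in 1 fit over all 8 libraries and 1 to 4 without a library. The 248 genes that differed between the lines became 405 with GC trends removed and 95 (without QSG control 2) to 930 (without LX-2 control 2). The number of LX-2 lists that passed, 4, became 2 with quantile normalization, 0 with an estimated correlation and 1 with fry, and 1 (without mimic 1) to 6 (without control 1, where collagens and proteases also passed) without a library. The 9 QSG lists became 5 with a filter at 5 RPKM, 5 in 1 fit over all 8 libraries, 0 with an estimated correlation and 0 with fry. The LX-2 seed-site difference of -0.0353 (LX-2 seed-site genes) became -0.0895 with 8mer sites only, -0.0467 to -0.0238 without a library and -0.0270 with fold changes regressed on UTR and transcript GC, UTR length and expression. That of QSG, -0.0005, became 0.00043 without the filter, 0.00024 with a filter at 5 RPKM and -0.0030 (without control 1) to 0.0020 (without control 2). The overlap between lines was 0 under each alternative run. More genes tested without the filter, and fewer libraries, are part of these settings; beyond that the cause was not tested.

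Across all genes, same-numbered libraries did not deviate together (correlation -0.0586 in LX-2 and -0.0545 in QSG). A correlation over all genes cannot exclude an effect of the replicate number on some of them. With the replicate number as a block the counts were 446 in LX-2, 1 in QSG and 105 for the difference, and 3 LX-2 lists passed. That block ended the limma call of ITGB1 in LX-2 (adjusted p = 0.0544). It also ended the calls of the differences between the lines for ACOT8 (adjusted p = 0.106) and NT5DC2 (0.0998).

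Over the alternatives, values of named LX-2 genes kept their direction and side of the threshold in 586 cases, lost the call in 71, gained it in 10 and moved in 10. For QSG genes these were 323, 1, 6 and 23, for differences 170 and 15 lost, and for lists 482, 58, 8 and 20. No gene called changed sign. Among called QSG lists the medians of squamous markers without the filter (0.0025) and of mitotic genes without mimic 2 (-0.0061) did, and neither passed there. Where a library is left out, the lone library of its group is assumed to vary like the others. Sequencing depth is unknown, so what it limits could not be given.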

Other observations

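The gene lists and tests described here were all chosen after the data were seen. The 19 genes of antigen presentation by MHC class I, which shares no member with the 24 lists fixed beforehand, were measured in LX-2, and 8 rose (13 adjusted over the list alone; median log2 fold change 0.40, camera p of 7.0e-12, 0.0599 with an estimated correlation, fry p of 0.0106). The peptide transporter genes TAP1 (10.1 to 20.4 RPKM, log2 fold change 0.97) and TAP2 (0.78) rose most, followed by B2M (758 to 1161 RPKM, 0.61), HLA-B (0.61), HLA-C (0.54) and the immunoproteasome gene PSMB9 (0.53). Of the 8 that rose, 3 (TAP1, TAP2 and PSMB9) carry AGTACAAA in the 3' UTR. Members that were not called were not checked for it. Of 17 measured in QSG none passed in limma or adjusted over the list alone (median -0.01), and the lines differed (median LX-2 minus QSG 0.38, camera p of 1.6e-11, 0.0209 with an estimated correlation). Without LX-2 mimic 1 or mimic 2, 1 gene was called.

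Contractile genes that the serum response factor controls leaned the other way. Of 21 measured in LX-2, 19 had a negative fold change and 4 fell, ACTA2, TAGLN, MYL9 and the factor's own gene SRF (15.4 to 9.93 RPKM, -0.58), or 8 adjusted over the list alone (median -0.19, camera p of 1.5e-05, 0.164 with an estimated correlation, fry p of 0.0457). The median was -0.10 without LX-2 control 1, -0.30 without control 2 and -0.12 with GC trends removed. The list was chosen after ACTA2, TAGLN and MYL9 had been seen, and 9 members are in lists fixed beforehand. Among the 12 measured members in none of those, 11 were negative (median -0.24, camera p of 0.00069, 0.183 with an estimated correlation). In QSG no member passed in limma (median -0.02, camera p of 0.0894, 0.208 with an estimated correlation, fry p of 0.0468). Without LX-2 mimic 1 no member was called, and without mimic 2 it was 1.

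Genes with TACCAGT, the seed match of a strand fully complementary to miR-150-5p, were low in LX-2 after the regression on 3' UTR and transcript properties (-0.0284, rank 5 of 15842 heptamers from the lowest), but not before it (-0.0033, rank 6398). The hypothesis that a passenger strand of the mimic may lower them was tested by comparing genes with the octamer TACCAGTA against genes with the heptamer alone. The adjusted means were -0.0380 (274 genes, SE 0.0141) and -0.0213 (906 genes, SE 0.00946), a difference of -0.0167 (SE 0.0170). This is within its error, so the hypothesis stays open.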
